A study of Mus musculus with 5 samples.

How the data were processed

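Single-nucleus RNA sequencing (10x Genomics droplets) was run on nuclei from the kidneys of male mice that carried the transgenes Six2-TGC, Rosa26rtTA and pTRE-H2BeGFP, in which doxycycline food (625 mg per kg) labels the chromatin of nephron cells with a green fluorescent histone (GFP). Nuclei were sorted for DNA stain and then for GFP. There were 5 libraries, 1 for each group. They held GFP-negative and GFP-positive nuclei from kidneys without injury, and GFP-positive nuclei 64 h, 96 h and 28 d after bilateral ischaemia-reperfusion injury (IRI), made by clamping both renal pedicles. The submitters gave the same serum values for both libraries without injury, so these were not treated as separate animals. The sample labels call them uninjured whereas the series' design text mentions sham surgery, so it is unclear whether these animals were operated on, and every fold against them carries this limit.

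The deposited matrices hold unique molecular identifier (UMI) counts per gene and nucleus, which the authors obtained with bcl2fastq 2.17, STAR 2.5.1b and Cell Ranger 2.1 on the mm10 mouse genome with a pre-mRNA reference. Each deposited matrix was checked to match its lists of barcodes and of 27998 genes, and its counts were read as whole numbers. The rule by which the authors called barcodes was not stated. The authors' merging of the libraries in Seurat was not used, and their cell type calls were not analysed here. Gene symbols came from the deposited gene lists, where 56 symbols stood for more than 1 gene. Their counts were kept apart by Ensembl identifier. Coordinates of named genes came from GENCODE mouse release 21, which uses the same genome build, and 62 of 62 genes looked up were matched by identifier. Pairs of libraries shared at most 20 barcodes.

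Barcodes with at least 200 detected genes and at most 10% mitochondrial UMIs were kept. Scrublet scores were computed within scanpy 1.11.5 at an expected doublet rate of 0.03. The caller marked under 0.5% of barcodes in every library, 5 of 3339 at most, so its calls were not used and the planned run with calls kept was identical to the reported values. Counts were normalised to 10000 per nucleus and log-transformed, 2000 variable genes were chosen with the library as batch key, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 followed, with seed 0 and without integration across libraries. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for trimmed mean of M-values (TMM) factors.

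Clusters were named after the most similar of 18 marker classes. Each class was scored as the mean, over its markers, of the log2 ratio of the cluster's level to the 25th percentile of all clusters, with 10 counts-per-million units (CPM) added to both. A name needed at least 3 detected markers, and no other class with more of its markers among the 10 leading genes of the cluster. It also needed a score margin of 0.3 over the next class. Clusters without an own marker but with at least 3 genes of the tubule injury list among the 10 leading genes were left unnamed. So were clusters over 1.5 times as deep as their libraries whose next class scored over 1.5. This scoring replaced a simpler one that misnamed proximal tubule clusters, and its limits were set after the data had been seen. Names carry the suffix "-like" because they rest on transcripts alone. Proximal tubule (PT) and thick ascending limb (TAL) nuclei are those in clusters with these names. The plan counted injured PT clusters as PT, but the single cluster led by injury genes had parietal epithelium as its most similar class and stayed unnamed. Values with this cluster added are given for the injury, gluconeogenesis, glycolysis and inflammatory lists, for Havcr1 shares and for some checks.

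For PT-like and TAL-like nuclei, UMIs were summed per library, divided by the total of the sum and expressed as CPM. Ratios of an IRI library to the GFP-positive library without injury carry an exact conditional interval for a ratio of Poisson counts. The log2 folds use a pseudocount of 1 CPM. Levels carry exact Poisson intervals, and shares of nuclei carry exact Clopper-Pearson binomial intervals. All intervals are at 95% and cover counting error only, since each group had 1 library. No test of a difference between groups was therefore possible, nothing could be paired, and no p-value, standard error or number of changed genes is given. "Higher" and "lower" describe the libraries at hand. Where a gene had 0 UMIs in the reference sum, a lower bound on the fold was computed against 3 counts of that sum.

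There were 22 gene lists. They covered gluconeogenesis, glycolysis, glucose and fructose transport with fructolysis, lactate and pyruvate handling, glutamine and ammoniagenesis, the pentose phosphate pathway, the citric acid cycle, fatty acid oxidation, the nuclear-encoded respiratory chain, mitochondrially encoded transcripts, the hypoxia response, PT transport and endocytosis, tubule injury and dedifferentiation, inflammatory signals, profibrotic signals and matrix, proliferation, immediate early and heat shock genes, antioxidant and iron handling, PT transcription factors, the S1 and S2 segments, the S3 segment and cytosolic ribosomal proteins. Ccn1, a member of the profibrotic list, was not found under that symbol. Members with at least 20 UMIs over both sums counted as measured. A list is described by its median log2 fold and by the members at least 1.5-fold higher or lower. The interval of a median came from redrawing the counts of its members from Poisson distributions. Each median was also placed among 10000 random lists of the same size, in which each member was replaced by a gene among the 50 nearest in expression.

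The lists, marker classes, comparisons, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each IRI time, the 8 genes at each end of the log2 fold among those with at least 100 UMIs and 20 CPM in the higher PT sum, a set of 25 genes of glucose metabolism, injury, PT identity and fatty acid oxidation, and 2 to 4 members with the largest folds of each list described. The GFP sort used 8 genes at each end over all nuclei. Further list members named in the text, such as Cubn, Vegfa and Hmox1, were chosen after their values were seen. Some genes that the rule took are not reported. Shares of PT-like nuclei with a UMI of a gene were computed after thinning each nucleus at random to 600 UMIs, with shallower nuclei left out. Connecting tubule-like and intercalated cell-like nuclei served as the background for free RNA. After the data had been seen, the difference in the summed CPM of a list was compared between classes, with intervals from counts redrawn from Poisson distributions.

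Alternatives changed 1 choice at a time. They covered the scaling (TMM, median-of-ratios factors, or totals without mitochondrial genes and without the 20 most abundant genes), no barcode filter or a strict one (400 genes, 5% mitochondrial), Leiden resolutions 0.5 and 2.0, a class call per nucleus without clustering from at least 3 marker UMIs, all GFP-positive nuclei, a mean over nuclei, thinning to 300, 600 or 1000 UMIs, a pseudocount of 5 CPM, and other gene filters. Alternatives chosen after the data had been seen added the injury-led cluster, left out a cluster led by S3 segment genes, left out the 3% of barcodes with the highest doublet scores, summed PT nuclei thinned to 300 UMIs, and left out a TAL-like cluster without a TAL marker among its 10 leading genes where at least 50 nuclei remained. The fold estimates were tested on simulated data with 50 genes for each true fold. True folds of 4, 2, 0.5 and 0.25 were recovered at medians of 3.91, 2.02, 0.523 and 0.280, so the strongest decreases came out too small, and 96% of the intervals held the true value for each. Of 200 unchanged lists of 13 genes, 2.5% lay outside the middle 95% of random lists. The simulated counts were Poisson draws from the profile of all GFP-positive nuclei without injury, at the totals of that library and of the 64 h library. Only 200 genes were changed. The simulation thus did not cover the smaller PT and TAL sums, many shifted genes or list members that vary together.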

Results

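Nuclear RNA was counted in 5 libraries of single kidney nuclei, 1 per group, so no group had a replicate and all intervals below are 95% intervals for counting error alone. The libraries without injury came from animals with a serum creatinine of 0.122 mg/dL and a blood urea nitrogen of 26.1 mg/dL. After ischaemia-reperfusion injury the creatinine was 0.375 mg/dL at 64 h, 0.312 mg/dL at 96 h and 0.144 mg/dL at 28 d, and the urea nitrogen was 37.0, 91.8 and 31.7 mg/dL. The GFP-negative library held 3339 barcodes and 3846624 UMIs, with a median of 964 UMIs and 622 genes per nucleus. The GFP-positive library without injury held 3508 barcodes and 7153971 UMIs, with medians of 1793.5 UMIs and 992.5 genes. At 64 h there were 3012 barcodes and 4500630 UMIs, with medians of 1290 UMIs and 837 genes. The 96 h library was the shallowest, with 3508 barcodes, 1922002 UMIs and medians of 484 UMIs and 358.5 genes, and 306 of its barcodes fell under 200 genes, which left 3202. At 28 d there were 3299 barcodes and 3767530 UMIs, with medians of 982 UMIs and 626 genes. Mitochondrial transcripts made up between 0.0498% and 0.155% of the UMIs of a library. A gene with 0 UMIs over all nuclei of a library could have had a level of up to 0.780 CPM in the GFP-negative library, and up to 0.419, 0.667, 1.56 and 0.796 CPM in the GFP-positive libraries from no injury to 28 d.

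The comparison of GFP-positive with GFP-negative nuclei from kidneys without injury asked which cell types the label separated. Sorting for GFP gave mostly nephron nuclei. PT-like nuclei made up 65.5% (63.9 to 67.0) of the GFP-positive library and 11.5% (10.4 to 12.6) of the GFP-negative library. Endothelium-like nuclei made up 1.31% and 23.6% (22.1 to 25.1), fibroblast and mural-like nuclei 0.884% and 16.9%, and collecting duct principal-like nuclei, which come from the ureteric bud and not from Six2 progenitors, 1.14% and 13.4%. Together, the nephron classes held 87.3% of GFP-positive and 35.6% of GFP-negative nuclei, and the stromal and immune classes 2.25% and 44.1%. The separation was incomplete for distal segments. TAL-like nuclei were 9.49% of the GFP-positive and 14.6% of the GFP-negative library, and distal convoluted tubule-like nuclei were 2.31% and 4.76%. Thin limb-like nuclei were 6.01% and 1.53%, connecting tubule-like nuclei 3.51% and 2.49%, intercalated cell-like nuclei 1.31% and 5.33%, and macrophage and dendritic-like nuclei 0.0570% and 3.57%. Of the 383 PT-like nuclei in the GFP-negative library, 208 lay in a cluster led by S3 segment genes, against 219 of the 2296 in the GFP-positive library. With barcodes of at least 400 genes and at most 5% mitochondrial UMIs, the endothelium-like share of the GFP-negative library was 11.7%.

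At the GFP-positive end of the sort, the glucuronosyltransferase genes Ugt2b37 and Ugt2b5 were 27.5-fold (21.5 to 35.8) and 21.5-fold higher over all nuclei, the sulfate transporter Slc13a1 14.0-fold, the cytochrome P450 gene Cyp4a12b 18.7-fold and the kynureninase gene Kynu 13.2-fold, followed by Clec2h at 13.4-fold and the unnamed transcript Gm13936 at 11.5-fold. Six2, the nephron progenitor factor whose lineage the label marks, was 43.3-fold (11.8 to 360) higher, from 161 UMIs against 2. The mice carried the Six2-TGC transgene, and the source of the Six2 UMIs was not tested. At the GFP-negative end, Rasgrp2 was 62.1-fold (26.1 to 194) higher, Slc43a3 44-fold, Ushbp1 38.5-fold, Shank3 35.9-fold, the endothelial transforming growth factor co-receptor gene Eng 33.0-fold, Adgrl4 26.9-fold and Ldb2 26.6-fold.

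**Figure D1:**
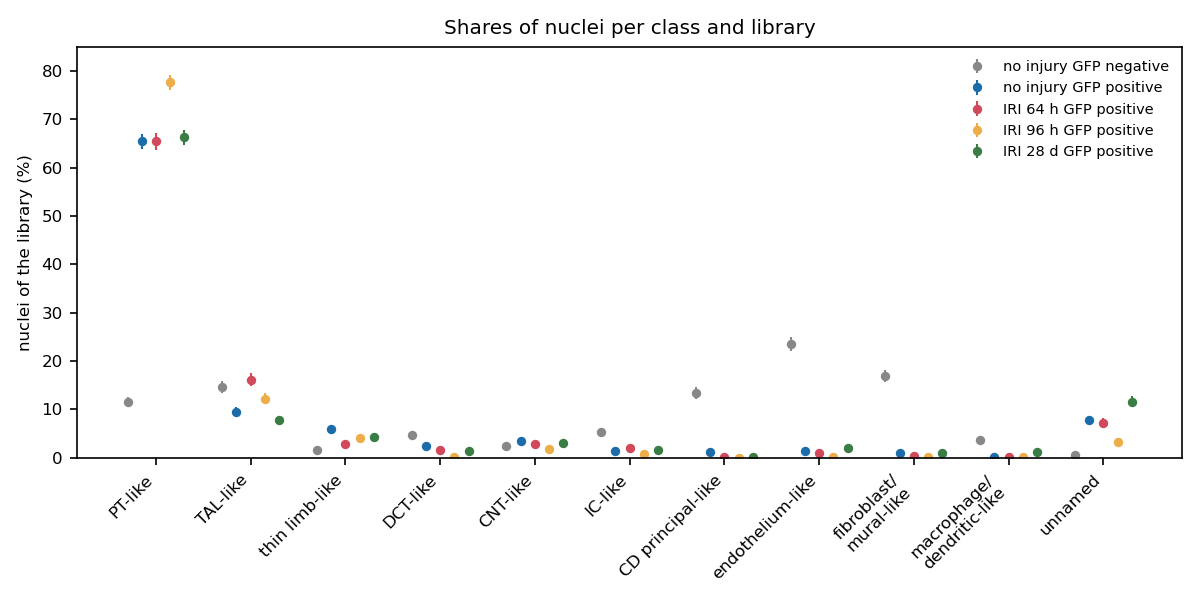
Share of nuclei (percent) in each marker class for the 5 libraries, with dots for the shares and bars for exact binomial 95% intervals. PT-like nuclei held 65.5% of the GFP-positive and 11.5% of the GFP-negative nuclei without injury.

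The GFP-positive time course asked how the composition of the labelled nephron differed after injury. PT-like nuclei were 65.5% (63.8 to 67.2) at 64 h, 77.7% (76.2 to 79.1) at 96 h and 66.3% (64.7 to 67.9) at 28 d. TAL-like nuclei were 9.49% (8.54 to 10.5) without injury, 16.1% (14.8 to 17.5) at 64 h, 12.1% (11 to 13.3) at 96 h and 7.73% (6.84 to 8.69) at 28 d. A TAL-like cluster led by the injury genes Lcn2 and Clu held 3 nuclei without injury, 295 at 64 h, 372 at 96 h and 139 at 28 d. It scored 2.81 for TAL and 2.38 for distal convoluted tubule, so it may also hold other distal nuclei. At a clustering resolution of 0.5 a connecting tubule-like cluster held 253 nuclei at 96 h. In the main clustering there were 55 connecting tubule-like and 2 distal convoluted tubule-like nuclei at that time. At a clustering resolution of 2.0 the TAL-like shares were 9.41% without injury, 7.40% at 64 h, 0.968% at 96 h and 4.27% at 28 d, because the nuclei of the cluster led by Lcn2 and Clu stayed unnamed. An unnamed cluster led by Vcam1, Cd44, Havcr1, Krt20 and Csf1, here called injury-led, held 2.28% of nuclei without injury, 6.64% (5.78 to 7.59) at 64 h, 3.15% at 96 h and 8.79% (7.85 to 9.81) at 28 d, and 0 of 3338 GFP-negative nuclei. The cluster led by S3 segment genes, which mark the straight end of the PT, held 6.24% without injury, 0.232% at 64 h, 0.812% at 96 h and 5.49% at 28 d. A larger PT-like cluster, with Slco1a1 and the S3 gene Slc7a13 among its leading genes, held 20.4% without injury, 1.16% at 64 h, 0 of 3202 nuclei at 96 h and 8.06% at 28 d.

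Thin limb-like nuclei were 2.72%, 4.00% and 4.18% at 64 h, 96 h and 28 d, distal convoluted tubule-like nuclei 1.66%, 0.0625% and 1.33%, connecting tubule-like nuclei 2.79%, 1.72% and 3.00%, and intercalated cell-like nuclei 2.06%, 0.750% and 1.52%. Collecting duct principal-like nuclei numbered 40, 7, 0 and 1 from no injury to 28 d, and macrophage and dendritic-like nuclei 2, 4, 3 and 36. Endothelium-like nuclei were 0.863%, 0.0937% and 1.97% of the IRI libraries. PT-like nuclei of different libraries lay largely in different clusters. At 96 h, 1767 of 2487 lay in a cluster led by Fgg, Brca2, Snx31 and C3, and at 64 h 1053 of 1973 in another. Neither had a PT marker among its 10 leading genes, as was also so for other PT-like clusters, such as that led by S3 segment genes. The main 96 h cluster had the lowest PT score of the PT-like clusters, 1.22, with parietal epithelium next at 0.572. The PT-like share at 96 h depended on this cluster, since at a clustering resolution of 0.5 it merged with the injury-led nuclei, stayed unnamed, and left a share of 23.8%.

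For PT-like nuclei, the series' subject of glucose metabolism after acute kidney injury was addressed by comparing each IRI library with the GFP-positive library without injury. Scaled by total UMIs, the median log2 fold of all measured genes was 0.17 at 64 h (11899 genes), 0.28 at 96 h (11615 genes) and 0.07 at 28 d (11601 genes). TMM scaling shifted every log2 fold by -0.22, -0.44 and -0.13 at these times. Of 66 list medians, 11 changed sign between scalings, and each is named with its list here. The percentile of a list compares it with genes of like expression that carry the same shift.

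Of the gluconeogenic transcripts, Pck1, G6pc, Fbp1 and Pcx were lower early after IRI. Pck1, the cytosolic phosphoenolpyruvate carboxykinase that commits carbon to glucose synthesis, was at 418 CPM without injury, 222 CPM at 64 h and 248 CPM at 96 h, ratios of 0.530 (0.484 to 0.579) and 0.592 (0.528 to 0.663). The glucose-6-phosphatase gene G6pc was at ratios of 0.623 (0.518 to 0.746) and 0.593 (0.460 to 0.756), and the fructose-1,6-bisphosphatase gene Fbp1 at 0.783 (0.725 to 0.845) and 0.534 (0.474 to 0.60). Pyruvate carboxylase, Pcx, was at 0.728 and 0.722. Within the same list, the glucose-6-phosphate transporter Slc37a4 was at 1.09 (0.929 to 1.28) and 1.29 (1.06 to 1.55). By 28 d, Pck1 was at 0.854 (0.787 to 0.925), G6pc at 1.06 (0.898 to 1.24), Fbp1 at 0.585 (0.534 to 0.642) and Slc37a4 at 1.9 (1.64 to 2.19).

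Over the 7 measured gluconeogenesis genes the median log2 fold was -0.35 (-0.47 to -0.24) at 64 h, with 2 members at least 1.5-fold lower and 1 higher, and it lay at percentile 1.45 of random lists. At 96 h it was -0.47 (-0.70 to -0.31), with 3 members lower and 0 higher, at percentile 3.77, which lies within the middle 95% of random lists. The 28 d median of 0.08 (-0.15 to 0.20) changed sign with TMM scaling, to -0.05. At a clustering resolution of 0.5, where most of the 96 h nuclei stayed unnamed, the 96 h median was 0.044.

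The glycolysis list had medians above the middle 95% of random lists at all 3 times, with fewer members higher at 28 d, where thinning to 600 UMIs gave a median of 0.21, inside the range of those lists. At 64 h, 8 of 13 measured members were at least 1.5-fold higher and 0 lower, with a median of 0.78 (0.61 to 0.91) at percentile 99.5. At 96 h these counts were 11 and 0, with a median of 1.32 (1.11 to 1.47) at percentile 99.9, and at 28 d 5 and 0, with a median of 0.50 (0.16 to 0.61) at percentile 99.5. The triose phosphate isomerase gene Tpi1 was 2.09-fold (1.83 to 2.39), 3.13-fold (2.71 to 3.61) and 1.55-fold (1.33 to 1.80) higher at 64 h, 96 h and 28 d. Aldolase A, Aldoa, was 1.81-fold, 2.92-fold and 1.45-fold higher, and the phosphofructokinase gene Pfkp 2.58-fold (1.98 to 3.38), 3.88-fold (2.92 to 5.16) and 1.74-fold (1.28 to 2.37). Lactate dehydrogenase A, Ldha, was at 1.75 (1.48 to 2.08), 2.52 (2.09 to 3.04) and 1.01, the pyruvate kinase gene Pkm at 1.76, 2.30 and 1.27, and Gapdh at 1.47, 5.26 (3.42 to 8.17) and 0.982. The hexokinases were scarce. Hk1 had between 21 and 24 UMIs per library, with ratios of 1.44, 2.93 (1.55 to 5.50) and 1.77, and Hk2 had 0, 1, 7 and 0 UMIs, at least 7.82-fold higher at 96 h. Over all GFP-positive nuclei, without a cell type call, the glycolysis median at 28 d was -0.02. In a check chosen after the data were seen, the summed glycolysis level at 96 h was 753 CPM (693 to 813) higher in PT-like nuclei and 530 CPM (319 to 741), 786 CPM (413 to 1191) and 809 CPM (496 to 1134) higher in TAL-like nuclei, in connecting tubule-like and intercalated cell-like nuclei and in thin limb-like nuclei. At 64 h these differences were 381 (344 to 419), -24.6 (-163 to 109), 147 (-16.2 to 307) and 362 (150 to 586) CPM, and 218 CPM (35.6 to 408) in TAL-like nuclei without the cluster led by Lcn2 and Clu, so a rise in PT was not separated from a rise shared by nuclei of a library.

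Glucose carriers differed in direction. Slc5a2, the sodium-glucose cotransporter of the early PT, was at 357 CPM without injury and at ratios of 0.380 (0.340 to 0.423), 0.484 (0.422 to 0.553) and 0.872 (0.799 to 0.95). Slc2a2, the basolateral glucose exporter, was at 0.944, 0.564 (0.467 to 0.677) and 0.574 (0.494 to 0.665), and Slc2a1, a glucose importer found on most cells, at 1.89 (0.994 to 3.63), 6.54 (3.72 to 11.8) and 1.41 (0.660 to 2.94). The list of glucose and fructose transport had medians of 0.08, 0.26 and -0.27, with TMM values of -0.14 at 64 h and -0.17 at 96 h, and 4 of 9 members were at least 1.5-fold lower at 96 h. At a clustering resolution of 0.5, Slc5a2 at 96 h was higher, with a log2 fold of 0.35.

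**Figure D2:**
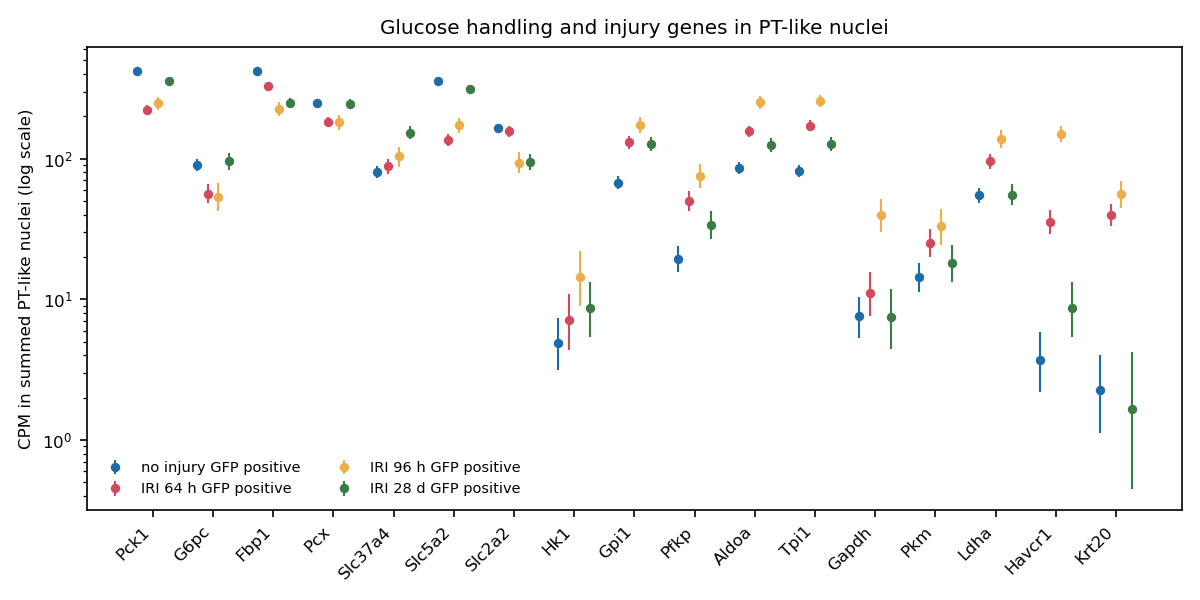
Level (CPM, log axis) of 17 genes in PT-like nuclei of the 4 GFP-positive libraries, with bars for exact Poisson 95% intervals. Pck1 was at 418, 222, 248 and 357 CPM from no injury to 28 d.

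Shares of nuclei were also computed at equal depth. Of PT-like nuclei thinned to 600 UMIs, 20.3% (18.7 to 22.0) held a Pck1 UMI without injury, 10.9% (9.56 to 12.4) at 64 h, 11.5% (9.49 to 13.8) at 96 h and 18.4% (16.6 to 20.2) at 28 d. In connecting tubule-like and intercalated cell-like nuclei, which mark the level of free RNA, the Pck1 share was 10.7% (6.44 to 16.3), 2.42% (0.502 to 6.91), 0 of 17 nuclei and 10.9%, so at 64 h the fall of the PT-like share was not separated from less free Pck1 RNA. For Fbp1 the PT-like shares were 21.7%, 15.8%, 10.8% and 13.2%, against 5.92%, 2.42%, 0 of 17 and 8.40% in the background nuclei. G6pc was seen in 4.44%, 3.42%, 3.05% and 5.63% of PT-like nuclei, against 1.18%, 0.806%, 0 of 17 and 2.52%. The 17 background nuclei at 96 h allowed shares of up to 19.5%. Median depths before thinning were 1933, 1361, 517 and 983 UMIs for PT-like and 1601, 1054.5, 435 and 1162 UMIs for background nuclei. Thinning left out 1601 of 2487 PT-like nuclei at 96 h.

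The pentose phosphate list also had medians above the middle 95% of random lists at all 3 times, and the glutamine list at 64 h. The pentose phosphate pathway, which makes NADPH and ribose, had medians of 0.67, 1.20 and 0.53 at percentiles 98.7, 99.8 and 99, with 4, 6 and 4 of 8 members at least 1.5-fold higher. Its transketolase Tkt was 3.04-fold (2.65 to 3.5), 4.51-fold (3.89 to 5.24) and 1.61-fold higher, and the phosphogluconate dehydrogenase gene Pgd 2.07-fold, 4.88-fold (3.99 to 5.98) and 1.74-fold. For glutamine and ammoniagenesis, 7 of 8 members were at least 1.5-fold higher at 64 h (median 0.84, percentile 99.6), while the medians of 0.65 at 96 h and 0.26 at 28 d (percentiles 90.1 and 87.9, with 4 and 3 members higher) lay within the middle 95% of random lists. The glutamine carrier Slc38a3 was at 2.21 (1.77 to 2.76), 4.54 (3.64 to 5.67) and 1.63, and the alanine aminotransferase gene Gpt2 at 2.38, 1.71 and 1.12. Lactate and pyruvate handling had medians of 0.14, -0.13 and -0.07, and the 64 h value was -0.08 with TMM scaling. At 96 h the lactate transporters Slc5a12 and Slc5a8 were at 0.317 (0.296 to 0.339) and 0.484, and the mitochondrial pyruvate carrier gene Mpc1 was at 0.545.

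Oxidative programmes went in several directions. The citric acid cycle had medians of 0.33, 0.02 and -0.07, with TMM moving the 96 h value to -0.42, and its malate dehydrogenase gene Mdh2 had log2 folds of 0.95 and 0.67 at 64 h and 96 h. Fatty acid oxidation had medians of 0.16, 0.14 and 0.06, each below 0 with TMM scaling (-0.05, -0.30 and -0.06). Within it, the peroxisomal bifunctional enzyme gene Ehhadh was at 0.246 (0.217 to 0.278), 0.225 (0.187 to 0.268) and 0.577 (0.524 to 0.633), while Hsd17b4, another peroxisomal enzyme, was at 1.98, 2.63 and 1.17. The carnitine palmitoyltransferase gene Cpt1a was at 1.13, 1.36 and 1.42, the lipid-sensing receptor gene Ppara at 1.64, 1.1 and 1.03, and its coactivator Ppargc1a at 1.41, 0.463 (0.399 to 0.535) and 0.973. The nuclear-encoded respiratory chain had medians of 0.80, 0.72 and 0.18, with 11 and 13 of 20 members at least 1.5-fold higher at 64 h and 96 h, led by Cox6c at 2.82 and 3.65. Mitochondrially encoded transcripts had a median of 1.17 (1.02 to 1.31) at 64 h, -0.59 (-0.98 to -0.31) at 96 h and 0.13 at 28 d. Cytosolic ribosomal protein genes had medians of 1.04, 1.22 and -0.12, with 16 of 16 members at least 1.5-fold higher at 64 h and at 96 h. The hypoxia response had medians of 0.23, 0.15 and -0.02, and the 96 h value was -0.28 with TMM scaling. In that list the vasodilator peptide gene Adm was at 5.35 (3.01 to 10.0) at 64 h and Vegfa at 0.594.

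Injury transcripts were high at 64 h and 96 h and nearer to the uninjured level at 28 d. Havcr1, which encodes kidney injury molecule 1, had 18, 105, 218 and 21 UMIs, with ratios of 9.60 (5.79 to 16.8), 40.6 (25.1 to 69.8) and 2.36 (1.20 to 4.69). The keratin gene Krt20 was at 17.7 (9.52 to 36.3), 24.7 (13.1 to 51.4) and 0.734 (0.171 to 2.48), the osteopontin gene Spp1 at 8.23 (7.43 to 9.13), 8.69 (7.79 to 9.71) and 1.81 (1.58 to 2.08), and the clusterin gene Clu at 9.64, 16.5 and 2.96 (1.78 to 4.96). Lcn2, which encodes a neutrophil gelatinase-associated lipocalin, had 0, 14, 36 and 1 UMIs, at least 7.68-fold higher at 64 h and at least 40.2-fold at 96 h. The progenitor factor Sox9 had 0, 3, 10 and 2 UMIs and was at least 11.2-fold higher at 96 h. The adhesion molecule Vcam1 was at 2.26 (0.829 to 6.48), 6.29 (2.5 to 17.1) and 3.53 (1.38 to 9.72), from 8 to 15 UMIs, and the strict barcode filter put it at a log2 fold of -0.11 at 96 h. The injury list had medians of 2.08, 2.90 and 0.55, unchanged with genes at 0 UMIs set to their bound, and 10 of 13, 12 of 13 and 6 of 12 members were at least 1.5-fold higher. With the injury-led cluster added to PT-like nuclei, the medians were 2.29, 2.87 and 1.14.

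In nuclei thinned to 600 UMIs, Havcr1 was found in 0.218% without injury, 1.87% (1.30 to 2.59) at 64 h, 7.11% (5.51 to 9.01) at 96 h and 0.365% at 28 d. The background nuclei had Havcr1 in 0 of 169, 1.61%, 0 of 17 and 0.840%, and these few nuclei allowed background shares of up to 5.70% at 64 h and 19.5% at 96 h. Krt20 was found in 0.261%, 1.97%, 3.39% and 0.104% of PT-like nuclei, against 0 of 169, 0.806%, 0 of 17 and 0.840%. Shares of Lcn2 (0 of 2296, 0.107%, 1.35% and 0 of 1918) and of the cycling gene Mki67 (0.131%, 0.640%, 0.339% and 0.0521%) did not exceed the background at 64 h, which was 1.61% for both. Lcn2 did not exceed it at 96 h either, where 1 of 17 background nuclei held it. Whether Lcn2 and Mki67 UMIs in background nuclei were free RNA or their own transcripts was not tested. Vcam1 stayed between 0.174% and 0.339%. The injury-led cluster had Vcam1, Havcr1 and Krt20 among its leading genes and was not counted as PT-like. Nuclei rich in these transcripts were thus left out by construction. That cluster held 2.28%, 6.64%, 3.15% and 8.79% of nuclei from no injury to 28 d. With it added, the Havcr1 shares were 0.379%, 3.19%, 9.72% and 1.28%.

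Inflammatory signals had medians of 0.77, 2.23 and 0.45, with 8 of 13, 13 of 14 and 4 of 13 members at least 1.5-fold higher. The macrophage growth factor gene Csf1 was at 9.78 (5.81 to 17.4), 19.1 (11.4 to 34.2) and 2.38, complement C3 at 3.18, 35.8 (21 to 65.4) and 3.37, and the cytokine gene Il34 at 2.25, 5.06 and 2.51 (2.19 to 2.88). Profibrotic signals and matrix had medians of 1.01, 1.22 and 0.24, with Cyr61 at 7.39 (5.87 to 9.39), 7.26 (5.63 to 9.43) and 2.13 and the platelet-derived growth factor gene Pdgfb at 2.30, 5.16 and 1.19. Proliferation had medians of 0.92 (9 of 13 members), 1.38 (8 of 11) and 0.04, the last at -0.07 with TMM scaling, and Top2a, a topoisomerase of dividing cells, was at 8.78 (4.26 to 20.4), 4.84 and 0.673. Immediate early and heat shock genes had medians of 0.54, 1.62 and 0.79, with Jund at 4.02, 10.1 (6.32 to 16.5) and 4.04 and the chaperone gene Hspa1a at 1.1, 1.96 and 4.54 (2.23 to 9.84). Antioxidant and iron handling genes had medians of 0.54, 1.05 and -0.01. The haem oxygenase gene Hmox1 was at 2.83, 4.90 and 1.12, and the ferritin gene Fth1 at 2.94 (2.85 to 3.02), 2.08 (2.00 to 2.15) and 0.460 (0.436 to 0.485).

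Transport and segment lists had medians below 0 at 64 h and 96 h. PT transport and endocytosis had medians of -0.37, -0.56 and -0.06, with 6 and 8 of 18 members at least 1.5-fold lower and 2 and 1 higher at 64 h and 96 h. The phosphate transporter Slc34a1 was at 0.649 (0.632 to 0.666), 0.642 (0.621 to 0.665) and 1.05, and the endocytic receptor genes Lrp2 at 0.831, 0.676 and 1.27 and Cubn at 1.02, 0.483 and 0.969. The 96 h median of this list was 0.08, and Slc34a1 had a log2 fold of 0.23, at a clustering resolution of 0.5. S1 and S2 segment genes had medians of -0.58, -0.88 and -0.19 (5, 8 and 2 of 10 lower), and S3 segment genes -1.12, -1.14 and -0.25 (8, 9 and 0 of 13 lower), with the S3-led cluster at 6.24%, 0.232%, 0.812% and 5.49% of nuclei. The PT-like cluster with Slco1a1 and Slc7a13 among its leading genes was at 20.4%, 1.16%, 0 of 3202 nuclei and 8.06%. The amino acid transporter Slc7a13 of the S3 segment was at 0.339, 0.200 and 0.826. PT transcription factors had medians of -0.10, -0.31 and 0.03, the last at -0.10 with TMM scaling. Hnf4a, a master regulator of PT identity, was at 0.984 (0.888 to 1.09), 1.11 (0.979 to 1.26) and 1.5 (1.36 to 1.65), while its relative Hnf4g was at 0.335, 0.399 and 0.866.

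**Figure D3:**
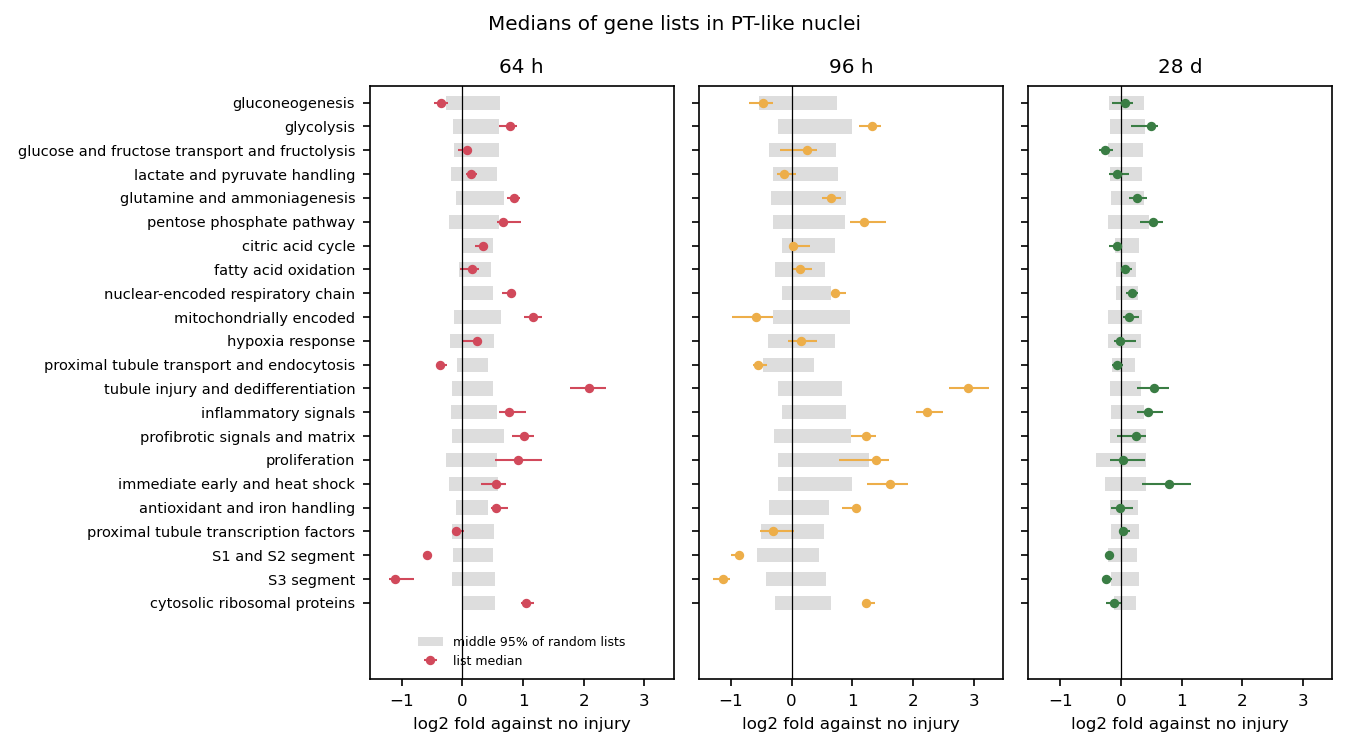
Median log2 fold in PT-like nuclei for 22 gene lists at 64 h, 96 h and 28 d, each dot with a line for its counting interval and a grey bar for the middle 95% of random lists, scaled by total UMIs. The glycolysis median was 0.78, 1.32 and 0.50, and 11 of the 66 medians change sign under other scalings.

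Among genes with at least 100 UMIs and 20 CPM in the higher PT sum, at this and the later times, the largest PT ratios at 64 h were those of the transcript 4930523C07Rik at 43.2 (16.4 to 162), Mid1 at 18.7 (17.3 to 20.4), Krt20, the actin-binding thymosin gene Tmsb10 at 16.7, the cytochrome P450 gene Cyp2a5 at 16.0 (10.7 to 25.0), Chst8 at 14.9, the carboxypeptidase N gene Cpn1 at 14.4 and Mrap2 at 10.9. At the low end were the oxysterol hydroxylase gene Cyp7b1 at 0.0104 (0.00607 to 0.0167), a transcript without a gene name at 0.0120, the complement gene C8a at 0.0163 from 1 UMI, the lipoprotein lipase gene Lpl at 0.0234 (0.0127 to 0.0394), Inmt at 0.0343, 4930533I22Rik at 0.0461, the organic anion transporter Slc22a7 at 0.0560 and Ctnna2 at 0.0612. Cyp7b1, Lpl, Slc22a7, C8a, 4930533I22Rik and Ctnna2 were leading genes of the S3-led cluster, whose share was 6.24% without injury and 0.232% at 64 h.

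In the same ranking at 96 h, the fibrinogen chain gene Fgg was 198-fold (53.6 to 1653) higher, from 2 and 118 UMIs. Havcr1, Tmsb10 at 38.3 and C3 at 35.8 came next, followed by Gm14582 at 27.0, Cdkl4 at 19.8, Snx31 at 19.5 and the DNA repair gene Brca2 at 19.3 (16.0 to 23.3). The lowest were Lpl at 0.0102 (0.00210 to 0.0299), the anion transporter Slco1a1 at 0.0312, the same unnamed transcript at 0.0327, 4930533I22Rik at 0.0564, Slc22a7 at 0.0570, Ctnna2 at 0.0623, Gm16004 at 0.0648 and Cyp7b1 at 0.0662. Lpl, 4930533I22Rik, Slc22a7, Ctnna2 and Cyp7b1 were leading genes of the S3-led cluster, whose share was 0.812% at 96 h. Slco1a1 and Gm16004 were among the leading genes of a PT-like cluster with 714 nuclei without injury and 0 at 96 h. Without the S3-led cluster, Cyp7b1 at 96 h had a log2 fold of 0.48.

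At 28 d the largest ratios of this ranking were smaller. Mid1, a ubiquitin ligase gene of microtubules, was at 11.6 (10.7 to 12.7), and it was also higher in other classes at 64 h and 28 d, with intervals above 1 in 15 of 15 pairs of class and time. The reductase gene Akr1c19 was at 5.40, Scand1 at 5.24, the phospholipid exporter gene Abcb4 at 5.17, Gabrb1 at 4.66, the thioesterase gene Acot9 at 4.06, Six2 at 4.04 (3.17 to 5.17) and Ak7 at 3.66, and Six2 was also at 4.81 and 7.98 at 64 h and 96 h. Whether the Six2 UMIs came from the gene or from the Six2-TGC transgene was not tested. The lowest were the potassium channel gene Kcnj2 at 0.0956 (0.0431 to 0.185), Lpl at 0.160, Akr1b3 at 0.185, Lin7a at 0.230, Kcnq1 at 0.245, the water channel Aqp2 at 0.263, Pcdh17 at 0.267 and Gm26632 at 0.269. Aqp2 marks collecting duct principal cells, which gave 40 nuclei without injury and 1 at 28 d. Akr1b3, a marker of the thin limb class, was a leading gene of an unnamed cluster with 76 GFP-positive nuclei without injury and 0 at 28 d. Whether free RNA from such nuclei set these PT ratios was not tested.

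On mm10, Pck1 (ENSMUSG00000027513) lies on chromosome 2 from 173153048 to 173159273, G6pc (ENSMUSG00000078650) on chromosome 11 from 101367561 to 101377903, and Fbp1 (ENSMUSG00000069805) on chromosome 13 from 62864753 to 62888282. Slc5a2 (ENSMUSG00000030781) lies on chromosome 7 from 128265657 to 128272430, Havcr1 (ENSMUSG00000040405) on chromosome 11 from 46735080 to 46779578, and Mid1 (ENSMUSG00000035299) on chromosome X from 169685199 to 170005736. Cyp7b1 (ENSMUSG00000039519) lies on chromosome 3 from 18071950 to 18243338, Lpl (ENSMUSG00000015568) on chromosome 8 from 68880491 to 68907448, and Six2 (ENSMUSG00000024134) on chromosome 17 from 85684277 to 85688274.

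For TAL-like nuclei, largely different clusters were set against each other. The cluster led by Lcn2 and Clu, with no TAL marker among its 10 leading genes, supplied 295 of 486 TAL-like nuclei at 64 h, 372 of 389 at 96 h and 139 of 255 at 28 d, against 3 of 333 without injury. Its scores of 2.81 for TAL and 2.38 for distal convoluted tubule were close, so these sums may include other distal nuclei. The injury list had medians of 2.23, 2.26 and 1.32 at 64 h, 96 h and 28 d. Without that cluster, an alternative chosen after the data were seen, they were 0.93 (0.41 to 1.48) at 64 h and -0.08 (-0.65 to 0.33) at 28 d, and the 17 nuclei left at 96 h were not compared. Lcn2 had 1 UMI without injury and was at ratios of 42.8 (7.38 to 1719), 124 (21.4 to 4994) and 12.6, and Clu was at 21.8 (11.3 to 48.1), 37.8 (19.4 to 84.3) and 8.90 (4.23 to 20.9). The glycolysis list had TAL medians of -0.10 (-0.32 to 0.25), 0.55 (0.17 to 0.86) and -0.20 (-0.67 to 0.32), and Ldha was at 1.07, 1.09 and 1.11. Without the cluster led by Lcn2 and Clu, the glycolysis median was 0.27 (-0.10 to 0.57) at 64 h and 0.10 (-0.61 to 0.45) at 28 d. At 64 h, fatty acid oxidation had 11 of 21 members at least 1.5-fold lower and a median of -0.59 (-0.75 to -0.16), but without the cluster led by Lcn2 and Clu it was -0.22 (-0.49 to 0.07). The median at 96 h was -0.54, at percentile 2.55 and within the middle 95% of random lists, and at 28 d it was -0.08. PT marker lists were lower in the same TAL sums, with medians at 64 h and 96 h of -1.13 and -0.82 for S1 and S2 segment genes, -0.97 and -1.47 for S3 segment genes and -0.37 and -0.48 for PT transport, so less free RNA from PT nuclei was not separated from lower levels in TAL cells. The mitochondrial regulator Ppargc1a was at 0.547 (0.482 to 0.622), 0.263 (0.201 to 0.340) and 0.695 (0.587 to 0.821), and the acyl-CoA dehydrogenase gene Acadm at 0.415, 0.484 and 0.943. The pentose phosphate pathway had medians of 0.97, 1.45 and 1.17 over 4, 4 and 3 measured members. Gluconeogenesis had TAL medians of -0.43 (-0.91 to -0.02), 0.02 (-0.60 to 0.41) and 0.43 (-0.27 to 0.87) over 4, 4 and 5 measured members. The 64 h median lay within the middle 95% of random lists. A lower gluconeogenesis level confined to PT-like nuclei at 64 h was thus not separated from one shared with other nuclei. TMM scaling shifted the TAL folds by -0.05, -0.26 and -0.16. Differences between TAL-like and PT-like nuclei in these lists were not tested.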

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

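Of the tests in this part, those of the S3-led cluster, of injury state within PT-like nuclei alone and without Itgb6, which had a high baseline, of glycolysis by injury state, of shared, mitochondrial and ribosomal RNA and of a rise of Mid1 confined to PT were chosen after the result was seen, as were the values that decided the other Mid1 tests. Median differences between times in mitochondrially encoded and ribosomal protein transcripts were taken up because they pointed in opposite directions at different times. Mitochondrially encoded transcripts had a PT median log2 fold of 1.17 at 64 h and of -0.59 at 96 h. Cytosolic ribosomal protein genes had PT medians of 1.04 at 64 h, 1.22 at 96 h and -0.12 at 28 d. These differences between times were not tested, since each time had 1 library.

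Free cytoplasmic RNA that differed between libraries was weighed as a candidate explanation for the mitochondrial and ribosomal shifts. More of it with mitochondrial transcripts would reach all nuclei of the 64 h library, but the mitochondrially encoded median in TAL-like nuclei was -0.095 (-0.42 to 0.14), below the PT interval of 1.02 to 1.31, which argues against it. At 96 h the summed mitochondrially encoded level differed from no injury by -335 CPM (-378 to -292) in PT-like, -691 CPM (-846 to -539) in TAL-like and -576 CPM (-766 to -373) in thin limb-like nuclei and by -425 CPM (-652 to -186) in connecting tubule-like and intercalated cell-like nuclei, as less free mitochondrial RNA in that library would make it, so this stays open. The ribosomal protein median in TAL-like nuclei was 0.76 (0.43 to 0.93) at 64 h and 1.30 (0.94 to 1.55) at 96 h, but the summed level rose by 771 CPM (613 to 929) and 1758 CPM (1482 to 2036) there against 2017 CPM (1941 to 2092) and 2456 CPM (2345 to 2564) in PT-like nuclei, which argues against an equal amount in all nuclei as the whole of the PT rise. With 844 CPM (618 to 1079) in connecting tubule-like and intercalated cell-like and 2443 CPM (2095 to 2797) in thin limb-like nuclei at 64 h, a shared part stays open, as does a difference in the cells after injury or between animals, which was not tested.

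In PT-like nuclei at 64 h and 96 h, 8 and 11 of 13 glycolysis genes were at least 1.5-fold higher while 2 and 3 of 7 gluconeogenesis genes were at least 1.5-fold lower, with a median within the middle 95% of random lists at 96 h, and the loss of S3 nuclei, the injury state of single nuclei and RNA shared by all nuclei were weighed as candidate explanations. Without the S3-led cluster the gluconeogenesis median was -0.39 (-0.49 to -0.26) and -0.49 (-0.67 to -0.31), which argues against the loss of that cluster as the source of these medians. Another PT-like cluster, with Slco1a1 and the S3 gene Slc7a13 among its leading genes, held 714 nuclei without injury, 35 at 64 h, 0 at 96 h and 266 at 28 d. It stayed in the sums, so a loss of S3 nuclei outside the S3-led cluster was not tested. Among PT-like nuclei thinned to 600 UMIs, the summed gluconeogenesis level of nuclei with an injury list UMI over that of nuclei without was 0.882 (0.798 to 0.975) at 64 h and 0.947 (0.803 to 1.12) at 96 h, so a link to the injury state may hold at 64 h and stays open at 96 h, while for glycolysis the ratios of 1.13 (0.990 to 1.29) and 0.994 (0.840 to 1.18) left it open. The gluconeogenesis ratio was 1.00 (0.917 to 1.09) without injury and 0.971 (0.875 to 1.08) at 28 d, without Itgb6 it was 0.867 (0.783 to 0.959), 0.912 (0.776 to 1.07) and 0.860 (0.748 to 0.986) from 64 h to 28 d, beside 1.15 (1.01 to 1.30) for glycolysis at 64 h (with Itgb6 1.18, 1.01 to 1.37, at 28 d), and with the injury-led cluster added, which was set apart by injury genes, it was 0.844 (0.764 to 0.932), 0.909 (0.772 to 1.07) and 0.841 (0.761 to 0.929). The summed glycolysis level at 96 h was higher by 530 CPM (319 to 741) in TAL-like and by 809 CPM (496 to 1134) in thin limb-like nuclei, against 753 CPM (693 to 813) in PT-like nuclei, as RNA shared by all nuclei would make it, and at 64 h by -24.6 CPM (-163 to 109), or 218 CPM (35.6 to 408) without the cluster led by Lcn2 and Clu, by 362 CPM (150 to 586), and by 147 CPM (-16.2 to 307) in connecting tubule-like and intercalated cell-like nuclei, against 381 CPM (344 to 419), so shared RNA stays open at both times beside a response of several cell types.

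Mid1 was 18.7-fold higher in PT-like nuclei at 64 h and 11.6-fold at 28 d, but at a ratio of 0.929 at 96 h (down to 0.496 in other classes), and a response of PT cells, free RNA and a difference shared by all nuclei of a library were weighed as candidate explanations. In TAL-like nuclei the ratio was 14.5 (12.0 to 17.6) at 64 h, in endothelium-like nuclei 14.9 (9.33 to 24.8), and in 15 of 15 pairs of another class with 64 h or 28 d it was between 3.76 and 29.1 with an interval above 1, which argues against a response of PT cells alone. At 64 h the TAL level was 172% (164 to 180) of the PT level, which argues against free RNA from PT nuclei, although the bound set beforehand, more than 2 times the highest share of a PT transport gene, was not reached because Slc9a3 stood at 305% against a list median of 9.97%. The TAL ratio at 28 d, 6.76 (5.47 to 8.41), was close to the bound of 0.5 times the PT ratio set beforehand and did not decide. A difference between libraries or between animals, whose Mid1 may vary because the gene spans the pseudoautosomal boundary of the mouse X chromosome, therefore cannot be told apart from a response of all kidney cells, because each time had 1 library.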

How the results depend on the processing

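The alternatives with the injury-led cluster, without the S3-led cluster, without the highest doublet scores with summed nuclei thinned to 300 UMIs and without the TAL cluster led by Lcn2 and Clu were chosen after seeing the data. Unless construction is named, the cause was not tested. Among PT gene levels 4431 values stayed within their counting interval, 825 moved beyond it and 8 reversed, not all of them named here. Among PT list medians these counts were 923, 257 and 2, and of the other results 283, 126 and 3. Leaving out the top doublet scores moved none of the values.

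Scaling moved the early medians. Gluconeogenesis at 64 h was -0.57 with TMM and -0.55 with median-of-ratios factors or without mitochondrial and abundant genes, and glycolysis 0.57, 0.59 and 0.59. At 96 h TMM and median-of-ratios gave -0.90 and -0.87 for gluconeogenesis and 0.88 and 0.92 for glycolysis, and a pseudocount of 5 CPM gave 1.06 for glycolysis.

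A resolution of 0.5 merged the main 96 h PT cluster with the injury-led one and left both unnamed, so by construction other nuclei remained at 96 h. Its PT share was then 23.8%, with medians of 0.044 for gluconeogenesis, 1.09 for glycolysis and 0.076 for PT transport, and Slc5a2 (0.35) and Slc34a1 (0.23) reversed. The PT shares at 64 h and 28 d were 59.9% and 64.0%. At resolution 2.0 the PT shares were 60.0% at 64 h and 69.7% at 96 h.

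Over all GFP-positive nuclei the gluconeogenesis median at 64 h was -0.51 and the glycolysis median 1.01 at 96 h and -0.018 at 28 d, and Slc16a7 at 28 d reversed to -0.49. By calls per nucleus, gluconeogenesis at 96 h was -0.27 and Slc16a7 at 28 d also -0.27. Thinning to 600 UMIs gave gluconeogenesis at 96 h as -0.77, and glycolysis at 28 d as 0.21, within its counting interval. Thinning to 300 gave glycolysis as 1.06 at 64 h and 0.68 at 28 d. Adding the injury-led cluster gave gluconeogenesis at 64 h as -0.49. Leaving out the S3-led cluster reversed Serpina1f at 64 h (0.016) and Cyp7b1 at 96 h (0.48), both leading genes of that cluster.

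The strict filter reversed Vcam1 at 96 h (-0.11) and gave PT shares of 14.4% in the GFP-negative library, 61.7% at 64 h and 75.3% at 96 h, and GFP-negative shares of 11.7% for endothelium and 18.1% for TAL. No filter gave 70.9% PT at 96 h. Calls per nucleus gave PT shares of 77.2% and 13.8% in the GFP-positive and GFP-negative libraries without injury, and 68.0%, 59.1% and 80.1% at 64 h, 96 h and 28 d.

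Without the TAL cluster led by Lcn2 and Clu, the TAL medians at 64 h were 0.27 for glycolysis, 0.14 for the citric acid cycle and -0.022 for immediate early genes, the last 2 reversed, and the injury median at 28 d reversed to -0.079. The TAL shares were 12.7% without injury, 13.7% at 64 h, 6.18% at 96 h and 9.85% at 28 d at resolution 0.5, and 7.40%, 0.968% and 4.27% after IRI at resolution 2.0. Calls per nucleus gave 12.5% at 64 h and 4.65% at 96 h, the strict filter 2.85% at 96 h and 5.65% at 28 d, and no filter 14.5% at 96 h.

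The Havcr1 share without injury was 0.610% unthinned. At 64 h it was 3.29% at 1000 UMIs, 4.71% unthinned, 2.81% by calls per nucleus and 3.19% with the injury-led cluster, and at 96 h 4.07% at 300 UMIs, 9.68% at 1000 UMIs and 9.72% with that cluster. At 28 d it was 0.869% unthinned, 0.807% by calls per nucleus and 1.28% with that cluster.

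Depth limited the 96 h library most, where 1601 of 2487 PT-like nuclei had under 600 UMIs and 17 background nuclei remained after thinning. Whether depth moved the levels was not tested, since thinning leaves the expected share of each gene unchanged.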

Other observations

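The values in this part were chosen after the data were seen, and no explanation was tested for them. The injury-led cluster had lower levels of Pck1, Fbp1 and G6pc than PT-like nuclei of the same library, and other gluconeogenesis genes were not compared. Pck1 was at 128, 72.2, 108 and 132 CPM there from no injury to 28 d, against 418, 222, 248 and 357 CPM in PT-like nuclei. Fbp1 was at 229, 86.6, 130 and 76.5 CPM against 423, 331, 226 and 247 CPM. G6pc was at 33.6, 4.12, 0 and 16.7 CPM against 90.5, 56.4, 53.7 and 95.7 CPM, and its count of 0 at 96 h allowed a level of up to 39.9 CPM. At 28 d this cluster was the largest group outside the named classes, with 290 of 3299 nuclei. With it added to PT-like nuclei, the gluconeogenesis medians were -0.49, -0.51 and -0.08, those of glycolysis 0.76, 1.27 and 0.47 and those of inflammatory signals 0.99, 1.87 and 1.29. Whether its nuclei come from the proximal tubule was not tested. Its score was highest for parietal epithelium, at 1.96, without a marker of that class among its 10 leading genes. At a clustering resolution of 2.0, a cluster with Vcam1 and Cd44 among its leading genes scored 1.68 for parietal epithelium and 1.16 for PT. A separate cluster of 58 nuclei, with Ncam1 and Akap12 among its leading genes, scored 3.32 for parietal epithelium.

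TAL-like nuclei gave further values outside glucose metabolism, but the cluster led by Lcn2 and Clu supplied 295 of 486 of them at 64 h and 372 of 389 at 96 h, against 3 of 333 without injury. Profibrotic signals had medians of 2.03, 1.53 and 0.38 at 64 h, 96 h and 28 d, and inflammatory signals 1.55, 0.69 and 0.57. Without that cluster these medians were 0.45 and 0.47 at 64 h. The osteopontin gene Spp1 was at ratios of 8.57, 4.50 and 2.53. Within fatty acid oxidation, the mitochondrial trifunctional protein gene Hadha was at 0.559, 0.587 and 0.449, whereas the peroxisomal enzyme gene Hsd17b4 was at 2.06, 1.97 and 1.77. Of the pentose phosphate genes, Tkt was at 1.91, 2.64 and 2.74 and Pgd at 2.09, 6.13 and 2.11. Cytosolic ribosomal protein genes had TAL medians of 0.76, 1.30 and 0.23 and mitochondrially encoded transcripts -0.09, -1.19 and 0.20.

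Unnamed nuclei made up 7.73% of the GFP-positive library without injury, 7.24% at 64 h, 3.28% at 96 h and 11.5% at 28 d, and 0.569% of the GFP-negative library. Besides the injury-led cluster they held a cluster of 115, 18, 4 and 91 nuclei with markers of both TAL and PT, and a cluster of 76 nuclei that occurred in the library without injury among the 4 GFP-positive ones. In PT-like nuclei, the iron storage genes Fth1 and Ftl1 at 28 d were at 0.460 (0.436 to 0.485) and 0.455 (0.426 to 0.485) of their level without injury, after 2.94 and 1.94 at 64 h.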
